A study of Homo sapiens with 18 samples.

How the data were processed

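RNA levels were measured on whole-transcript human gene expression arrays in H295R cells, an established line from a human adrenocortical carcinoma that makes steroid hormones. Per the labels, the cells carried a stable, non-inducible pcDNA4 vector that was either empty (control cells) or encoded GRα, the ligand-binding isoform of the glucocorticoid receptor (gene NR3C1). Per the labels' protocols, cells at 70% confluence were kept without serum for 24 h and then treated for 6 h with dexamethasone at 100 nM, RU486 at 100 nM or ethanol vehicle, and biotinylated cDNA was made from 100 ng of total RNA with random hexamers. Dexamethasone is a synthetic glucocorticoid agonist, and RU486 (mifepristone) binds the receptor as an antagonist or partial agonist.

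The values used are log2 values that the authors deposited as 1 table of 29153 probe sets. Per the submitters' processing notes, the tools were RMA, which corrects background, quantile-normalizes arrays and summarises probes into probe sets, and limma. Versions, settings and a genome build are not given in the sources used here. Quantile normalization forces the arrays to a common distribution, so a shift of most RNAs in one direction would not appear in these values. The deposited log2 values ran from 2.07 to 14.15, and the median of an array lay between 6.28 and 6.35 over all probe sets. The table holds values for 17 of the 18 arrays described. The column of GRα cells with RU486, replicate A, is empty, and per the labels that array failed quality control.

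Groups were taken from the labels: 3 arrays each of control vehicle, control dexamethasone, control RU486, GRα vehicle and GRα dexamethasone, and 2 of GRα RU486. No arrays held identical values. The labels call the samples biological replicates without saying whether they were separate cultures, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays, 2 or 3 in a group, limits the precision.

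Probe sets were named with the platform's annotation, updated by Entrez number through a RefSeq gene table, which matched 19429 of the 19460 probe sets with 1 symbol. Another 1754 probe sets had several symbols and 7939 had none, and both kinds stayed out of the gene tests. Of several probe sets for a gene (769 genes), the one with the highest mean over all arrays was used, which left 18417 genes. FKBP5 and CYP21A2 share their probe sets with other genes and NR0B1 had no probe set of its own, so these genes are not analysed here. The RefSeq table served only for names and for which genes neighbour each other.

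Each comparison was a contrast in 1 limma fit (version 3.58.1, R 4.3.3) over all 17 arrays with a mean per group, with 11 residual and 5.89 prior degrees of freedom. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 18417 genes of a comparison. The 9 contrasts were GRα against control cells in vehicle, each ligand against vehicle in each line, the difference between the lines in each ligand's effect, and dexamethasone against RU486 in each line. Errors of log2 fold changes are standard errors (SE) from this fit. Gene lists (22, with 413 of 446 distinct genes measured) were tested with camera from limma at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

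Groups, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names NR3C1 and 17 further receptor targets and steroidogenic genes in every comparison. It adds the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between the groups, the 5 largest each way for a difference between lines, and up to 4 called members of each list, some being left out for length. Alternatives were another quantile normalization, median centring, leaving out the dimmest genes, trend and robust options of eBayes, array weights, other gene units, fitting only the groups compared, the replicate letter as a block, stricter thresholds and leaving out each array. Comparisons that use the same vehicle arrays share their chance values, so 1000 simulations of unchanged groups gave the correlation that sharing alone produces if all arrays of a gene vary alike.

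The fit was tested on simulated data with the means and spreads of the 18417 genes, 200 of them changed. In the simulated dexamethasone comparison of GRα cells it called 89% of genes changed by 0.5 log2 and 100% of those changed by 1 log2, with 9 false calls among 198. In the simulated RU486 comparison of GRα cells, with 2 arrays, these shares were 84% and 100%. All simulated arrays of a gene had the same spread, and fewer changed genes would make the adjusted threshold stricter. These shares therefore do not say how many RU486 effects would be called in the real arrays.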

Results

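The series holds 17 arrays of H295R adrenocortical cells in 6 groups, made by crossing 2 stable lines (GRα and empty-vector control) with 3 treatments of 6 h (vehicle, dexamethasone and RU486). Over all genes, arrays of the same line correlated at 0.987 to 0.997 and arrays of different lines at 0.971 to 0.977, and the first principal component, with 69.4% of the variance, separated the lines. GRα vehicle replicate B lay farthest from the arrays of its line, with the lowest array weight of the set (0.19). It held more histone RNA than replicates A and C, with a median difference of 0.568 log2 over 58 histone genes.

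NR3C1, which encodes the glucocorticoid receptor, was higher in every GRα array than in every control array. Its log2 value was 7.94 ± 0.04 (SD, n = 3) in vehicle-treated GRα cells and 7.36 ± 0.07 (SD, n = 3) in vehicle-treated control cells, a 1.5-fold difference (log2 0.59 ± 0.07 SE, limma adjusted p = 1.37e-06). Neither ligand gave a call for NR3C1 in either line. The probe set was not tested for telling the transgene from the endogenous RNA.

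**Figure D1:**
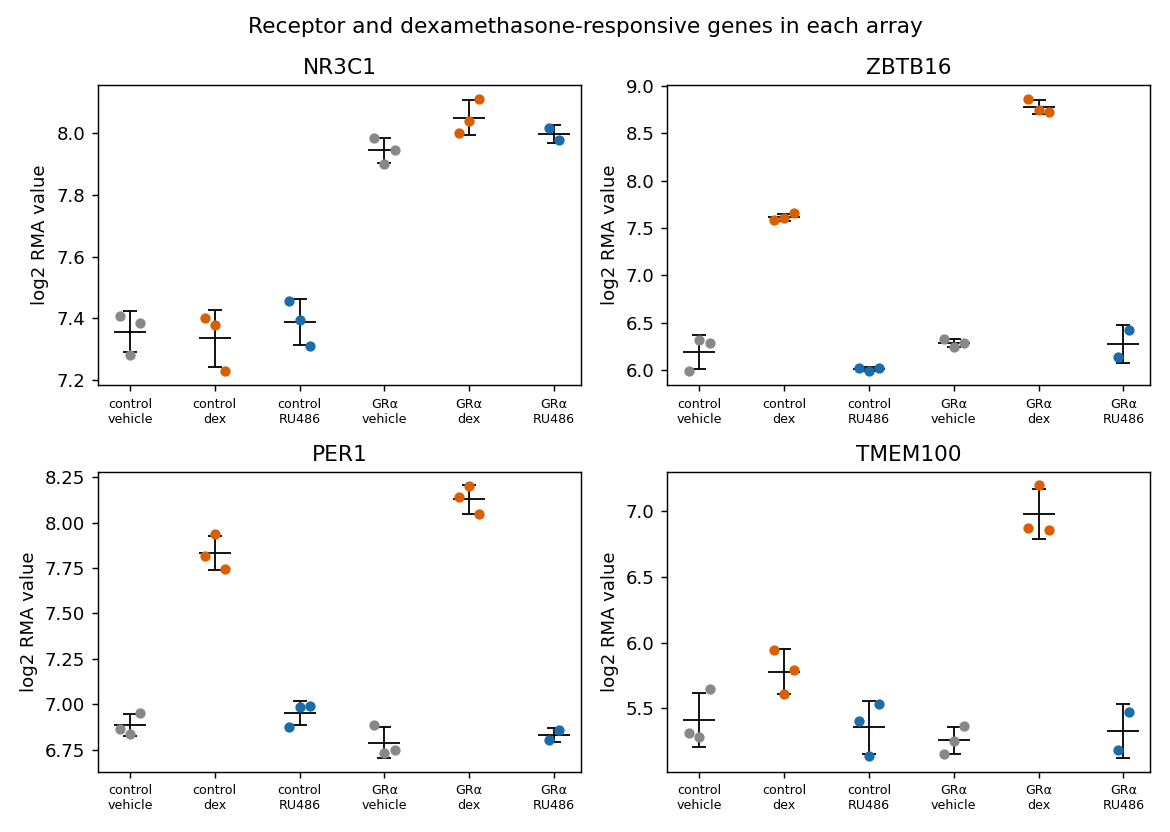
Log2 RMA values of NR3C1, ZBTB16, PER1 and TMEM100 (vertical axes) in each of the 6 groups (horizontal axes), with a point per array, a bar at the mean and whiskers of 1 SD. NR3C1 is higher in all GRα arrays than in all control arrays, and ZBTB16 rises from 6.29 to 8.78 with dexamethasone in GRα cells and from 6.20 to 7.62 in control cells.

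The comparison of the lines in vehicle asks what differs between GRα and control cells without added ligand. ANXA2, which encodes the membrane-binding protein annexin A2, was 24.7-fold higher in GRα cells (log2 9.52 ± 0.09 against 4.89 ± 0.24, SD, n = 3 each). The growth cone protein gene GAP43 (17.3-fold), NELL2 (14-fold), the secretory granule gene CHGB (7.75-fold) and the glutamate receptor subunit gene GRIA2 (7.16-fold) were also higher. GABRG1, a subunit of the GABA-A receptor, was 17.9-fold lower, and the adhesion genes CDH9 (9.35-fold), FAT4 (9.08-fold), PCDH20 (8.71-fold) and TNC (8.77-fold) and the gonadotropin-releasing hormone receptor gene GNRHR (7.29-fold) were lower as well. In all, 6144 of 18417 genes (33.4%) differed, 2771 higher and 3373 lower in GRα cells, with 232 and 203 of them at least 1 log2 apart. All folds are of array signal, and detection above background was not tested for low means such as those of GRIA2 in control cells (log2 4.10) and CDH9 in GRα cells (4.05).

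Further large rises were PRAME (log2 3.23 ± 0.07 SE), ADGRG2 (2.92 ± 0.08), AFF3 (2.79 ± 0.11) and CGNL1 (2.71 ± 0.09), and further falls were the zinc finger gene ZNF676 (−2.85 ± 0.17), the histone gene H3C11 (−2.73 ± 0.21), GPX7 (−2.63 ± 0.11) and VAMP8 (−2.45 ± 0.12). All had limma adjusted p-values under 0.05 and no overlap between the arrays of the lines. Groups of 3 arrays are free of overlap by chance in 10% of genes, and 40.5% of all genes were so here. The pseudogene ANXA2P2 (3.44 ± 0.13) resembles ANXA2 in sequence, so these signals are not independent.

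Genes for cholesterol synthesis and uptake were lower in GRα cells. Of 18 measured members, 16 fell and 1 rose, and adjusted over the list alone 17 fell and 1 rose (camera adjusted p = 8.87e-10; adjusted p = 0.105 with an estimated correlation). The lanosterol synthase gene LSS fell by 1.67 ± 0.07 SE on the log2 scale, SCARB1, which encodes a lipoprotein receptor, by 1.01 ± 0.06, DHCR7, the last step of cholesterol synthesis, by 0.97 ± 0.09 and NSDHL by 0.90 ± 0.06. The exception was SQLE, the squalene epoxidase gene, which rose by 0.26 ± 0.06.

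Of 15 targets of Wnt/beta-catenin signalling, 9 rose and 2 fell, and adjusted over the list alone 9 rose and 3 fell (camera adjusted p = 3.90e-04; adjusted p = 0.105 with an estimated correlation). APCDD1 (log2 1.91 ± 0.06 SE), NKD1 (1.43 ± 0.07), RNF43 (0.90 ± 0.07) and NOTUM (0.83 ± 0.09), which encode inhibitors of the pathway, rose. LGR5 (−0.31 ± 0.08) and the Wnt antagonist gene DKK1 (−0.45 ± 0.07) fell. Of 10 metallothionein genes, 5 rose and none fell, with 6 rises adjusted over the list alone (camera adjusted p = 0.0329; adjusted p = 0.402 with an estimated correlation). MT1X rose by 0.55 ± 0.08. Without GRα vehicle replicate B, 3 of the 5 rises were still called (MT1E, MT1F and MT1X), MT2A and MT4 having adjusted p-values of 0.0974 and 0.272.

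Steroidogenic genes went both ways, with 4 of 19 higher and 7 lower, or 4 and 10 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0914). HSD3B2, the adrenal 3β-hydroxysteroid dehydrogenase, was 3.0-fold lower, the aromatase gene CYP19A1 3.13-fold lower, SULT2A1, which sulfates DHEA, 2.12-fold lower and STAR, which carries cholesterol into mitochondria, 1.87-fold lower. CYP17A1 was 1.17-fold higher, a call that held in 2 of 6 fits without a single array (adjusted p up to 0.122). CYP11A1 (log2 0.09 ± 0.08 SE), CYP11B1 (−0.03 ± 0.12), CYP11B2 (0.00 ± 0.11) and MC2R (−0.02 ± 0.14) were not called. The steroidogenic regulator NR5A1 was 1.31-fold lower.

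Known glucocorticoid targets did not share a direction between the lines in vehicle. Of 38 glucocorticoid-induced genes, 11 were higher and 5 lower in GRα cells, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.189). SGK1 was 1.78-fold, DUSP1 1.21-fold and KLF9 1.20-fold higher, TSC22D3 was 1.57-fold lower, and PER1 (log2 −0.10 ± 0.07 SE) and ZBTB16 (0.09 ± 0.09) were not called. No list of markers of chromaffin, fibroblast, endothelial, leukocyte or epithelial cells was called in this comparison, the lowest camera adjusted p being 0.0784 for fibroblast markers. Each line is 1 stable line, so the effect of the receptor and other differences between the lines cannot be told apart here.

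**Figure D2:**
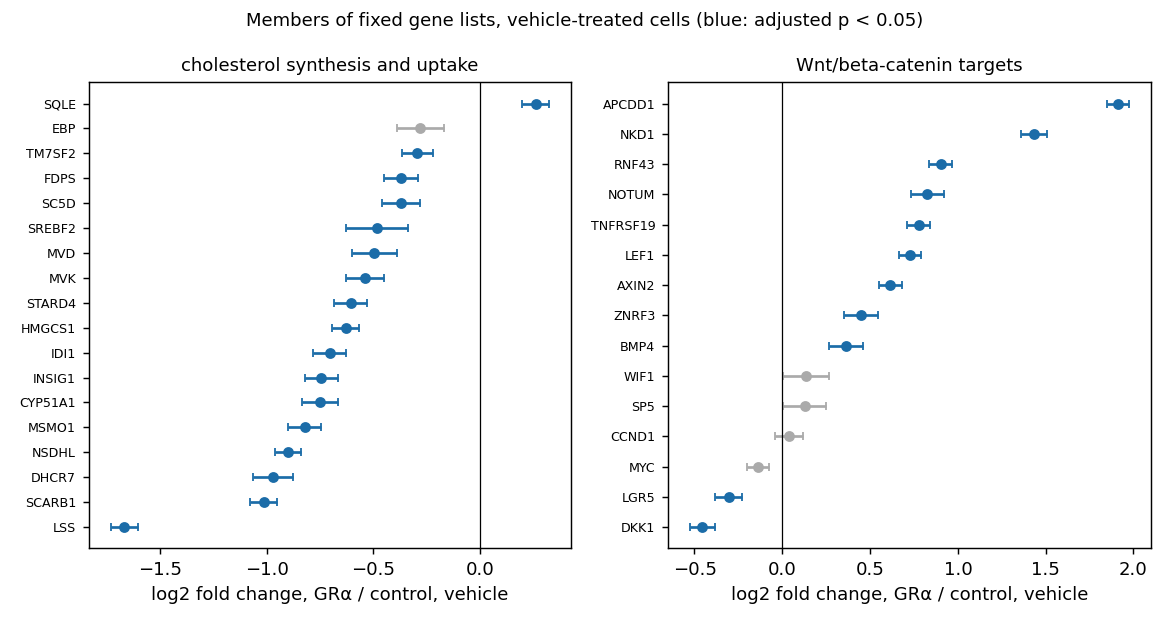
Log2 fold change of GRα over control cells in vehicle (horizontal axes) for each measured member (vertical axes) of the lists for cholesterol synthesis and uptake (left) and Wnt/beta-catenin targets (right), with whiskers of 1 SE from limma, in blue where the adjusted p was under 0.05. On the left 16 of 18 genes are lower in GRα cells at that threshold, and on the right 9 of 15 are higher.

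Dexamethasone against vehicle in GRα cells asks which RNAs respond to the agonist within 6 h where the receptor is over-expressed. ZBTB16, a zinc finger transcription factor gene known to respond to glucocorticoids, rose 5.63-fold (log2 8.78 ± 0.08 against 6.29 ± 0.04, SD, n = 3 each). TMEM100 rose 3.30-fold, the olfactory receptor genes OR7A5 and OR7C1 3.21-fold and 2.25-fold, the Ras exchange factor gene RASGRF1 3.04-fold, the sulfate transporter gene SLC26A2 2.95-fold, the clock gene PER1 2.53-fold, PRKCH 2.25-fold, the ganglioside synthase gene ST3GAL5 2.12-fold and the vinculin gene VCL 2.11-fold. Falls were smaller, the largest being GRAP, an adaptor protein gene, at 1.83-fold, followed by OR7D4 (1.57-fold), BHLHA9 (1.56-fold), ID3 (1.54-fold), DUSP5P1 (1.53-fold) and PRSS35 (1.49-fold). The test called 372 genes, 250 up and 122 down, and 13 of the rises but 0 of the falls (limma) reached 1 log2.

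Of the 38 glucocorticoid-induced genes, 10 rose and 0 fell by limma, or 10 and 2 adjusted over the list alone (camera adjusted p = 1.20e-05; adjusted p = 0.0706 with an estimated correlation). Beside ZBTB16 and PER1 these included MAOA, the monoamine oxidase A gene (log2 1.01 ± 0.08 SE), ERRFI1, a feedback inhibitor of EGF receptor signalling (0.92 ± 0.06), and TSC22D3, also called GILZ (0.66 ± 0.11). DUSP1 (0.04 ± 0.08), KLF9 (−0.14 ± 0.07) and SGK1 (0.14 ± 0.07) were not called. The list's median change was 0.016, since most members moved little. In other lists NR5A1 (0.66 ± 0.08), LGR5 (0.75 ± 0.08), DUSP6 (0.58 ± 0.08), BCL2L1 (0.57 ± 0.08) and HERPUD1 (0.56 ± 0.07) rose. PNMT, the adrenaline-forming enzyme, fell by 0.40 ± 0.07, and GATA6 fell by 0.33 ± 0.07.

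No steroidogenic enzyme gene was called with dexamethasone in GRα cells: 0 of 19 members changed by limma, over all genes and adjusted over the list alone. STAR (log2 0.17 ± 0.07 SE), CYP11A1 (0.01 ± 0.08), CYP17A1 (−0.08 ± 0.08), HSD3B2 (−0.42 ± 0.15), CYP11B1 (−0.02 ± 0.12) and CYP11B2 (0.13 ± 0.11) stayed above an adjusted p of 0.05. Among 45 named calls, 19 of 23 rises and 4 of 22 falls held without each array in turn. GRAP, DUSP5P1 and PRSS35 held, while OR7D4 and GATA6 held in 4 of 6 such fits (limma adjusted p up to 0.103 and 0.0986). BHLHA9 and ID3 held in 2 of 6 (up to 0.127 and 0.134). In GRα cells GRAP, DUSP5P1 and PRSS35 were also lower with RU486 (log2 5.133, 5.944 and 6.002) than with vehicle (5.581, 6.307 and 6.335). Dexamethasone gave 4.706, 5.693 and 5.756, and RU486 gave no call. In control cells they stood at 5.32, 6.288 and 6.012 with vehicle and 5.276, 6.241 and 5.779 with dexamethasone. Leaving out single arrays cannot separate a response to dexamethasone from high values shared by the vehicle arrays. The total became 601 without GRα vehicle replicate C, 200 without GRα dexamethasone replicate B and 77 when only these 6 arrays were fitted.

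Dexamethasone against vehicle in control cells gives the response at the line's own receptor level. ZBTB16 rose 2.67-fold (log2 7.62 ± 0.04 against 6.20 ± 0.18, SD, n = 3 each), SLC26A2 2.43-fold, PER1 1.93-fold, the translation inhibitor gene PDCD4 1.69-fold, ST3GAL5 1.68-fold, OR7A5 1.66-fold and the interleukin-1 receptor accessory gene IL1RAP 1.65-fold. TSPYL2 rose 1.54-fold and CES1 1.53-fold. RANBP3L fell by 0.53 ± 0.08 SE on the log2 scale, the nuclear receptor gene NR4A3 by 0.46 ± 0.09 and the potassium channel gene KCNH5 by 0.45 ± 0.07. The test called 48 genes, 39 up and 9 down.

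Of the 38 glucocorticoid-induced genes 4 rose and 0 fell by limma, or 7 and 1 adjusted over the list alone (camera adjusted p = 7.42e-12; adjusted p = 0.00441 with an estimated correlation). Of the 19 steroidogenic genes, FDX1, which encodes the electron donor adrenodoxin, rose by 0.38 ± 0.07 SE, the 1 call of that list both over all genes and adjusted over the list alone. NR5A1 (0.34 ± 0.08) and TSC22D3 (0.25 ± 0.11) were not called. The total lay between 17 and 23 when any of the 6 arrays compared was left out and was 82 without GRα vehicle replicate B, which enters only through the shared spread. Of the falls named here RANBP3L held without each array, NR4A3 in none of the 6 such fits (limma adjusted p 0.11 to 0.283) and KCNH5 in 2 of 6. Among the rises, FDX1 held in none (limma adjusted p 0.0521 to 0.139) and CES1 in 2 of 6 (up to 0.217).

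The responses of the lines were compared directly. Of the 39 rises in control cells, 33 were also called in GRα cells, against 0.53 for independent lists, as were 7 of 9 falls, against 0.06. These comparisons share no arrays, but both use 1 estimate of each gene's spread. The calls are therefore not fully independent, and the values for independent lists may be too low. The 250 rises called in GRα cells had a median of 0.181 in control cells, and 219 of them (87.6%) were positive there. Over all 18417 genes the log2 fold changes correlated at r = 0.22 (Spearman 0.11) across genes, which are not independent replicates, and at 0.14 without control vehicle replicate B or GRα vehicle replicate C. Of the 39 rises in control cells, 30 were larger in GRα cells, with a median ratio of log2 fold changes of 1.31, while of the 9 falls 3 were larger there.

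A test of the difference between the lines called 12 genes, all with a larger rise in GRα cells. TMEM100 differed by 1.35 ± 0.18 SE on the log2 scale, ZBTB16 by 1.07 ± 0.12, RASGRF1 by 1.03 ± 0.14, OR7A5 by 0.95 ± 0.11 and NNMT, the nicotinamide N-methyltransferase gene, by 0.88 ± 0.13. The others were MAOA, SYDE2, VCL, LGR5, GREB1L, CSRNP1 and JADE1. PER1 (0.39 ± 0.10) and TSC22D3 (0.41 ± 0.16) were not called. The count was 6 without control vehicle A or C, control dexamethasone B or C or GRα dexamethasone B, 7 without GRα dexamethasone A and 5 when only the 12 arrays concerned were fitted; LGR5 held in 2 of 12 fits without a single array, with an adjusted p up to 0.183. Leukocyte markers were lower in this contrast by camera (adjusted p = 0.00425; adjusted p = 0.526 with an estimated correlation), with 0 of 12 members called by limma over all genes or adjusted over the list alone.

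**Figure D3:**
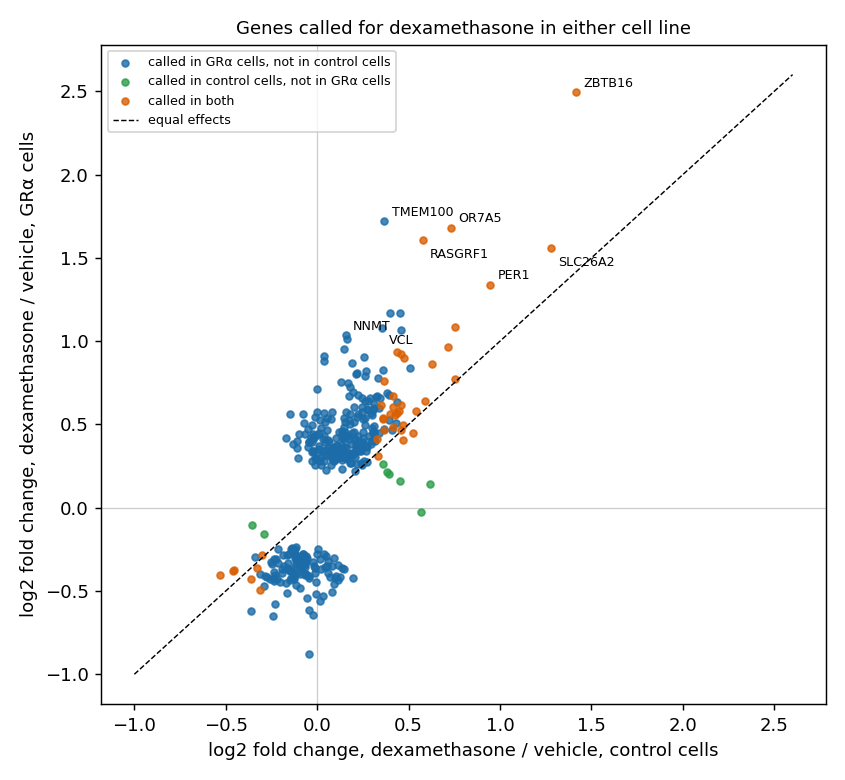
Log2 fold change with dexamethasone in GRα cells (vertical axis) against that in control cells (horizontal axis) for the genes called in either line, coloured by the line in which they were called, with a dashed line of equal effects. ZBTB16 lies at 2.49 in GRα cells and 1.42 in control cells, and TMEM100 at 1.72 and 0.37.

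RU486 against vehicle asks what the antagonist does on its own. The count was 0 by limma in GRα cells (3 vehicle and 2 RU486 arrays) and 0 in control cells (3 and 3), with 1572 and 621 genes at an unadjusted p under 0.05 where 921 are due by chance. In GRα cells ZBTB16 changed by −0.01 ± 0.10 SE on the log2 scale, PER1 by 0.04 ± 0.08, TSC22D3 by −0.09 ± 0.13 and STAR by 0.06 ± 0.08, none called. In control cells these values were −0.19 ± 0.09, 0.07 ± 0.07, −0.15 ± 0.11 and −0.07 ± 0.07. The difference between the lines in the RU486 effect gave 0 genes by limma, with 745 at an unadjusted p under 0.05. Without GRα RU486 replicate B, which leaves 1 array assumed to vary like the others, 1 gene was called in GRα cells, the small nucleolar RNA gene SNORD81 (log2 0.67, adjusted p = 0.0285, against 0.50 and 0.144 with all arrays), named after its value was seen.

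Genes that responded to dexamethasone were then followed in the RU486 arrays of the other line, which share no array with the comparison that chose them. The 250 rises of GRα cells had a median of −0.004 with RU486 in control cells (interquartile range −0.065 to 0.041), and the 39 rises of control cells a median of 0.015 with RU486 in GRα cells (−0.049 to 0.065). Within GRα cells the 250 rises had a median of 0.072 and the 122 falls −0.109 with RU486. Those comparisons share the vehicle arrays. Their correlation was 0.53 where unchanged groups gave 0.45 in simulation, with a covariance of 0.0101 against 0.00435. In control cells it was 0.39 against a simulated 0.50, with a covariance of 0.0034 against 0.00435. The simulation gave all arrays of a gene the same spread. The shared GRα vehicle arrays include replicate B, which had an array weight of 0.19. The excess in GRα cells and the medians of 0.072 and −0.109 therefore cannot separate an effect of RU486 from that array. No gene was called for both ligands in GRα cells, since RU486 had 0 calls by limma.

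Dexamethasone and RU486, a pair of steroids that bind the same receptor, were compared at the same dose of 100 nM and time of 6 h. In GRα cells ZBTB16 was 5.65-fold, OR7A5 3.33-fold, TMEM100 3.14-fold, SLC26A2 2.72-fold, RASGRF1 2.62-fold and PER1 2.46-fold higher with dexamethasone. MAOA was 2.03-fold and TSC22D3 1.68-fold higher, and ANP32D, PHLDA1 and MYB were 1.47-fold, 1.37-fold and 1.36-fold lower. The test called 165 genes, 137 higher and 28 lower with dexamethasone. Of the 38 glucocorticoid-induced genes 10 were higher and 0 lower by limma, or 11 and 0 adjusted over the list alone (camera adjusted p = 6.73e-12; adjusted p = 0.00434 with an estimated correlation). Of 14 named falls 1 held without each array in turn, PHLDA1; ANP32D held in 3 of 5 such fits, and MYB and TSC22D3 in 4 of 5. The total was 73 and 67 without RU486 replicates B and C, 102 without dexamethasone replicate B, 259 without GRα vehicle replicate B and 54 with only these arrays fitted.

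In control cells ZBTB16 was 3.04-fold, SLC26A2 2.33-fold, ST3GAL5 1.93-fold, PER1 1.84-fold and OR7A5 1.77-fold higher with dexamethasone than with RU486. NR5A1 was 1.42-fold higher, and RANBP3L, NR4A3, the annexin gene ANXA1 and the coactivator gene PPARGC1A were 1.41-fold, 1.40-fold, 1.38-fold and 1.33-fold lower. The test called 67 genes, 53 higher and 14 lower with dexamethasone. The glucocorticoid-induced genes were higher, 6 to 0 by limma or 10 and 1 adjusted over the list alone (camera adjusted p = 6.74e-15; adjusted p = 0.00165 with an estimated correlation). Wnt/beta-catenin targets were lower by camera (adjusted p = 0.0274; adjusted p = 0.469 with an estimated correlation), with DKK1 (−0.40 ± 0.07 SE) the 1 member called over all genes and adjusted over the list alone. Of the genes higher with dexamethasone in control cells, 43 of 53 were also called in GRα cells, against 0.39 for independent lists, and of those lower 6 of 14, against 0.021. Here too both comparisons use 1 estimate of each gene's spread. Of 10 named falls 2 held without each array in turn, RANBP3L and PPARGC1A; ANXA1 held in 3 of 6 such fits, DKK1 in 2 and NR4A3 in 1. The total was 29 to 39 without control dexamethasone A, B or C or control RU486 A or B, and 113 without GRα vehicle replicate B.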

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

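The following tests were chosen only after the result was seen: leaving out GRα vehicle replicate B for the difference between the lines, the tests of RNAs without poly(A) tails and of sample swaps for that array, and the use of quartiles to judge the levels of steroidogenic genes.

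The effect of dexamethasone differed between the lines in 12 genes, by a test of the difference itself. The differences, GRα minus control on the log2 scale, were 1.35 for TMEM100, 1.07 for ZBTB16, 1.03 for RASGRF1, 0.95 for OR7A5, 0.88 for NNMT, 0.85 for MAOA, 0.81 for SYDE2, 0.72 for VCL, 0.62 for LGR5, 0.59 for GREB1L, 0.59 for CSRNP1 and 0.53 for JADE1. When dexamethasone and vehicle were exchanged within each line, 9 of 100 splits, the real one included, gave at least 12 genes, the highest of the others giving 121, so chance was not excluded by this count. All 8 other splits as large kept the GRα arrays in their true groups and mixed the control arrays. They set the whole GRα effect against a control effect that was reduced and, in part of them, also reversed in sign. The 91 splits that mixed GRα arrays gave at most 6 genes.

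Among 9693 probe sets with no gene symbol or several, which no gene test used, 78 changed with dexamethasone in GRα cells (30 up, 48 down) and 1 in control cells (up), each against the vehicle arrays of its line.

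The 3-against-3 comparisons have 10 splits of their arrays, too few for a share under 0.05. The real split gave 6144 genes between the lines in vehicle, 372 and 48 with dexamethasone in GRα and control cells and 67 for dexamethasone against RU486 in control cells, and in each of these it was the 1 split of the 10 with as many, the highest other giving 0 by limma. For RU486 in control cells all 10 splits gave 0 by limma, with 621 genes at an unadjusted p under 0.05 in the real one. Every split but the real one mixes the true groups, so a real effect widens the spread there and lowers the count. These counts therefore cannot exclude chance.

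The wide difference between the lines in vehicle was weighed against receptor activity without added ligand, regional changes of the genome, a single array and a different cell type. Genes called for dexamethasone against RU486 in control cells numbered 67. Their difference between the lines, called or not, had the sign of the dexamethasone effect in 40.3% (27 genes). The exact binomial 95% interval was 28.5 to 53.0. This argues against receptor activity in the direction of dexamethasone as the main source. Between the lines 42 of the 67 were called, 16 of them with that sign, where 33.4% of all genes were called. The signs cannot address receptor effects in other directions. The count of 6290 without GRα vehicle replicate B argues against a single array. Neighbouring genes with different name stems correlated in their differences at 0.223 over 16335 pairs, above the highest of 100 shuffled orders (0.023), so regional copy number or silencing may account for part of the genes; the same measure was 0.087, 0.066 and 0.057 for dexamethasone in GRα and control cells and RU486 in control cells. The median percentile of 7 steroidogenic genes in vehicle-treated GRα cells was 76.5 (quartiles 31.3 and 92.8). By the limit on the median fixed beforehand, this counted against a different cell type. With the quartiles, added after the result was seen, the levels were too spread to exclude a different cell type by themselves. Control cells held low members too, MC2R at 24.5 (23.2 in GRα cells) and CYP11B1 at 36.8 (35.4), so this spread cannot decide the question. HSD3B2 (27.1 against 57.6), STAR (91.2 against 97.2) and NR5A1 (76.5 against 82) were lower in GRα than in control cells. CYP11A1 and CYP17A1 stood at percentiles 96.8 and 94.4 in GRα cells (10.25 and 9.76 log2). In control cells they stood at 96.6 and 92.1 (10.15 and 9.54 log2). Divergence of the stable lines and an effect of the receptor over a longer time stay open, since each construct is present in 1 line.

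GRα vehicle replicate B stood apart from replicates A and C, with histone RNAs higher by a median of 0.568 (55 of 58 genes). DNA-replication genes differed by a median of 0.071 (10 of 13 higher, range −0.293 to 0.202), which argues against more cells in S phase as the whole source and does not exclude a small part. A larger share of all RNAs without poly(A) tails would raise each class of them. Small Cajal body RNAs had a median difference of −0.034 (7 of 16 higher), which argues against it. The median was 0.17 for small nuclear RNAs (18 of 23 higher) and 0.051 for small nucleolar RNAs (96 of 176). Single RNAs differed more, RNU5D-1 by 1.97 and RMRP by 1.62, so a rise of some such RNAs in replicate B is not excluded. A swap with a control sample is not in line with its correlations, at least 0.987 with its own line and at most 0.974 with control arrays, nor one with a dexamethasone sample of its line with ZBTB16, which lay within 0.085 of replicates A and C. A swap with a GRα RU486 sample stays open, since replicate B correlated at 0.9894 and 0.9895 with those arrays and at 0.9897 and 0.9898 with replicates A and C and no gene was called between these groups, as does what raised the histone RNAs.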

How the results depend on the processing

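Leaving out GRα vehicle replicate B where it is not compared, leaving out arrays for the correlation between lines, and reading RU486 effects in the other line were chosen after seeing the data. Of 238 named calls under 3542 alternatives, none changed sign, 3136 stayed called and 406 lost the call; 162 were called under all. Named calls that differed between the lines in vehicle stayed called in 1533 of 1560. RU486 counts stayed 0 by limma in control cells and for the difference between lines under every alternative (unadjusted p under 0.05 in 621 and 745 genes), and in GRα cells (1572) except without an array, where they ran from 0 to 1.

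With a log2 change of at least 1 as well, counts became 435 between the lines in vehicle, 13 and 2 for dexamethasone in GRα and control cells, 3 for the difference between lines, and 11 and 2 for dexamethasone against RU486 in GRα and control cells. At an adjusted p under 0.01 the last 5 of these were 171, 16, 5, 83 and 37. These thresholds call fewer genes by construction. With only the compared arrays, which leaves fewer degrees of freedom, they were 77 and 23 for dexamethasone in GRα and control cells, 5 for the difference and 54 for dexamethasone against RU486 in GRα cells. Trend and robust options gave 74 in control cells, 19 for the difference and 107 for dexamethasone against RU486 in control cells, and array weights gave 148, 22 and 214; the cause was not tested. Without the dimmest genes, the latter was 103, with fewer genes tested.

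Without an array in turn, the counts ran from 5015 to 6290 between the lines, 200 to 601 and 17 to 82 for dexamethasone in GRα and control cells, 6 to 15 for the difference, and 67 to 259 and 29 to 113 for dexamethasone against RU486 in GRα and control cells. The upper values 82, 259 and 113 are those without GRα vehicle replicate B, which enters there only through the shared spread. The correlation of dexamethasone effects between lines, 0.22, ran from 0.14 to 0.27, and was 0.33 without the dimmest genes; the cause was not tested.

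Of the called lists, with an estimated correlation 0 remained between the lines (3 by preset camera), 0 for dexamethasone in GRα cells (1) and 0 for the difference (1), and 1 of 2 for dexamethasone against RU486 in control cells. Fry, which does not compare a list with other genes, called 18 between the lines, 0 for the difference and 1 for dexamethasone against RU486 in control cells. Without the dimmest genes 3 lists were called for dexamethasone in control cells, 0 for the difference and 4 for dexamethasone against RU486 in control cells, and another quantile normalization left 1 there; the cause was not tested.

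No pairing by replicate letter was seen over all groups: deviations of 40 same-letter pairs correlated at −0.25 to 0.32 (median −0.01, other letters 0.02), 5 above 0.1. Of 17 arrays 4 correlated best with their own letter. For dexamethasone and vehicle, same-letter pairs correlated at −0.02 to 0.32 in control and −0.09 to 0.1 in GRα cells. For RU486 and vehicle these ranges were 0.02 to 0.19 and −0.04 to −0.03. Whether samples were handled in lettered sets cannot be told from these values. With a replicate block the counts were 5967, 311, 35, 8, 137 and 55 in the order above, and 0 for RU486 by limma; the block moved no count by over 1.5 times and no list call. The overlap of dexamethasone and RU486 calls in GRα cells was 0 by limma at both thresholds. Detection above background was not tested, so a dim gene was not shown to be expressed.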

Other observations

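The region of small RNAs, its means per array and the windows of neighbouring genes were chosen only after results for their genes were seen. The fatty acid desaturase, receptor, transcription factor and OR7 genes were also chosen after their values were seen, and most lie outside the rule for named genes.

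Dexamethasone in GRα cells raised a neighbouring set of fatty acid desaturase genes, FADS1 (log2 0.48 ± 0.09 SE), FADS2 (0.73 ± 0.11) and FADS3 (0.58 ± 0.08), with limma adjusted p-values of 0.00757, 0.00126 and 0.000529 (n = 3 against 3). It also raised the interleukin-1 receptor genes IL1R1 (0.88 ± 0.11) and IL1RAP (0.97 ± 0.09), the NF-kB inhibitor gene NFKBIA (0.46 ± 0.07), the transcriptional repressor gene BCL6 (0.58 ± 0.08) and the receptor tyrosine kinase gene KIT (0.68 ± 0.06), while the transcription factor genes MYB (−0.43 ± 0.07) and SOX4 (−0.29 ± 0.06) fell. In control cells FADS3 (0.44 ± 0.08), IL1RAP (0.72 ± 0.09), MYB (−0.36 ± 0.07) and SOX4 (−0.30 ± 0.06) were called too, and IL1R1 stood at 0.03 ± 0.11, not called. The test of the difference between the lines called none of these genes, IL1R1 included. When each of the 6 arrays was left out in turn, the GRα calls of these genes all held except SOX4 (3 of 6), while in control cells IL1RAP held, FADS3 held in 1 of 6 fits (adjusted p up to 0.195) and MYB and SOX4 in none (up to 0.155 and 0.276). Of 16 measured genes and pseudogenes of the OR7 olfactory receptor family, OR7A5 (1.68) and OR7C1 (1.17) rose and OR7D4 (−0.65) fell with dexamethasone in GRα cells, at percentiles 13.4, 21.4 and 23.5 of mean signal among all genes, the call of OR7D4 holding in 4 of 6 such fits.

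Small RNAs of the imprinted region between DLK1 and DIO3 were higher with dexamethasone in GRα cells: 19 of 22 were positive, 8 of them called, among them MIR487A (0.62), SNORD114-26 (0.59) and MIR127 (0.57), with a median of 0.342. Without GRα vehicle replicate B the median was 0.331, so that array does not account for the rise. The median with all arrays lay at percentile 100 of 10000 random sets of small RNAs from elsewhere. The region was chosen after these values were seen, so this rank is no test of the rise. Small RNAs from elsewhere had a median of 0.007 in the same comparison, so a shift of all small RNAs does not account for the rise. In control cells, which share no array with that comparison, the median was 0.24, again at percentile 100, with 0 of 22 called by limma and 11 at an unadjusted p under 0.05, which is consistent with a response to dexamethasone in both lines. RNAs of 1 transcript move together, which random sets do not reproduce; the region's mean per array was higher in every dexamethasone array than in every vehicle array of its line, by 0.289 in GRα and 0.196 in control cells (SE 0.043 each), where chance gives such a separation in either direction in 10% of 3-against-3 comparisons. RU486 in GRα cells, against the same vehicle arrays, gave a median of 0.123 and means per array that differed by 0.094 without overlap, and dexamethasone against RU486 gave 0.198 with 0 of 22 called by limma and 8 at an unadjusted p under 0.05, while in control cells the means per array differed by 0.021 with RU486, with overlap, and by 0.176 for dexamethasone against RU486, without overlap.

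The region was lower in GRα than in control cells in vehicle, the window of 25 genes from DLK1 to MIR410 having a median difference of −0.432 with 25 of the same sign and 16 called, and its mean in every GRα dexamethasone array (5.818 to 5.913) lay below that in every control vehicle array (5.958 to 6.122). MEG3, which lies in that region, stood at 0.26 with dexamethasone in GRα cells (adjusted p = 0.086, not called), and whether the probe sets read mature small RNAs or their host transcripts was not tested.

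In windows of 25 neighbouring genes the highest median difference between the lines was 0.918, from TEX9 to VPS13C, with 21 genes called, and the lowest was −0.94, from ZNF737 to ZNF681, with 22 called, where 100 shuffled orders reached 0.32 in size. The last of these windows holds many zinc finger genes of similar sequence.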
